A study of Mus musculus with 6 samples.

How the data were processed

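RNA of mouse thoracic aorta was hybridized to 6 Illumina mouse bead arrays, on which each probe is read as the brightness of the beads that carry it. The samples came from male C57Bl/6 mice aged 3 to 4 months, 3 labelled wild type (WT) and 3 labelled as lacking Ndst1 in smooth muscle (Ndst1_SMKO, called mutant below). Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns and copied into biotinylated cRNA before hybridization.

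The deposited table of non-normalized values holds, per the file headers, an average intensity on a linear scale for each probe and array, not scaled between arrays. Beside each intensity the deposited table holds a detection p-value, per the file headers. GenomeStudio is named in the submitters' processing notes, with no version or step. A second deposited table, the authors' processed values, also holds intensities on a linear scale. Each of its columns ranked the probes exactly as the non-normalized column of the same sample did (Spearman correlation 1), and its medians were 135.8 to 135.9 for the WT arrays and 134.2 to 134.4 for the mutant arrays. These lie closer within a genotype than between, as if each genotype had been scaled on its own. How they were scaled is not given in the sources used here, so this table served only as an alternative, and differences between genotypes in it include any such scaling.

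Non-normalized intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected the background by normexp, with the background estimated from the detection p-values, added an offset of 16, applied quantile normalization and took log2. Because of the offset and the background that remains, fold changes of dim probes are understated. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays, whatever their genotype, were kept, which left 17954 of 45281. The median non-normalized intensity per array was between 130.0 and 141.5, and between 17549 and 18619 probes per array were detected. The number of arrays limits the precision: the median standard deviation between arrays of 1 genotype was 0.13 in log2 over the kept probes and 0.08 over the 5744 kept probes with a mean log2 value of at least 8.

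Probes were named from the platform annotation, in which 34885 probes had 1 gene, 18 had several and 10378 had none listed; probes with several or none were tested but not named. Symbols of 10 probes were updated through the RefSeq gene table, so that 19053 genes were named. Each gene was represented by its kept probe with the highest mean log2 value over the 6 arrays, without regard to genotype, which gave 10076 genes, and the text gives another kept probe of a gene for the cases that differed most. Ndst1 itself was not analysed here, so the genotype labels were not checked against the deleted gene.

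Mutant and WT arrays were compared per probe with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05 for the adjusted p. Differences are log2 values, mutant minus WT, with limma's standard error. For a gene detected on no array of 1 genotype only a bound is given. The bound sets the mean of the other genotype against the higher, on each array, of the gene's own value and the lowest value of any detected probe.

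Before the data were examined, 38 gene lists with 903 genes were fixed, of which 827 had a named probe. They cover heparan sulfate, matrix, muscle, signalling and metabolic genes, transcripts that respond to handling or time of day, and markers of other cell types that an aorta sample could hold. Lists with at least 5 kept genes were tested with camera (inter-gene correlation preset to 0.01), with Benjamini-Hochberg adjustment over the lists. Camera asks whether the mean test statistic of a list's genes lies above or below that of the other genes. A list said below to rank higher or lower differs in that mean, which a few strongly changed genes can carry. Camera with a correlation estimated per list and fry, which tests whether the genes of a list move one way on balance, were alternatives. The rule for named genes was also fixed then: the Ndst genes, the 12 largest rises and 12 largest falls among genes past the threshold whose 3 mutant values all lay on 1 side of the WT values, up to 4 genes per list with the smallest p, and for cell type lists also the 3 brightest. Genes named outside this rule are said to be so.

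The steps were tested on simulated arrays built from the probes and levels of this comparison. Background noise was added on top of the within-genotype spread, and probes varied independently of each other. The shares below therefore need not hold for the real arrays. Of probes changed by 0.5, 1 and 2 log2 units, 15.2%, 55.4% and 77.3% were recovered, and 5 of 21011 tested probes were called without having been changed. Of 38 simulated lists, the 3 shifted by 0.4 were called and none of the others.

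Alternatives changed 1 step at a time: no background correction, normexp with an offset of 50, no normalization between arrays, median scaling, the authors' processed values, no filter or a stricter filter that changed both the detection p (under 0.01) and the arrays required (all 6), eBayes with trend and robust settings, array weights, the replicate number as a block, the mean of a gene's probes, an unmoderated test per probe, and each array left out in turn. An alternative with the chip as a block was not run, since no chip is given in the sources used here. Counts without the genes of the cell type and handling lists, lists without the genes of the cell type lists, and the vascular tone list without 3 heart calcium genes were added after the data had been seen.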

Results

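Gene expression in the thoracic aorta was compared between 3 samples of mice lacking Ndst1 in smooth muscle and 3 WT samples, on 1 array each. Ndst1 encodes an enzyme of the Golgi that exchanges acetyl for sulfate groups on heparan sulfate, the sugar chain through which many growth factors and matrix proteins bind to cells. The deletion was driven by Cre under the SM22α promoter, and per the labels the WT mice carried no Cre, so the genotypes differ in Cre as well as in Ndst1. The title of the series places the comparison in a study of arterial elasticity. The labels do not say whether the 3 samples of a genotype came from separate mice, so the p-values measure only the spread between these samples. Values below are log2 differences, mutant minus WT, with their standard error, n = 3 arrays per genotype.

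Transcripts of heart muscle rose most in the mutant aortas, and genes of the acute phase response and of the circadian clock were among the largest falls. Myl7, an atrial myosin light chain, was 17.9-fold higher (4.16 ± 0.10, limma adjusted p = 3.67e-06). The other 11 largest rises were Sln (4.08 ± 0.09), Cox6a2 (4.06 ± 0.07), Csrp3, Actc1, Mybphl, Myh6, Ttn, Myl4, Tnnc1, Hamp and Mb (3.18 ± 0.11), most of which encode parts of the sarcomere or the energy supply of striated muscle. Another of the 3 probes of Ttn stayed at -0.04. Saa3, a serum amyloid of the acute phase, was detected on no mutant array and was at least 4.99-fold lower (adjusted p = 0.000109), and Mfsd2a, a lipid transporter, was at least 3.99-fold lower on the same terms (adjusted p = 0.000137). Dbp, an output gene of the clock, was 3.87-fold lower (-1.95 ± 0.08, adjusted p = 2.85e-05). Among the other largest falls were the acute phase genes Serpina3n (-1.93 ± 0.09), Lcn2 (-1.84 ± 0.10), Itih4 (-1.58 ± 0.08) and Fgl1 (-1.51 ± 0.10), then Nr1d1 (-1.44 ± 0.10), Lncbate10, Sik1 and Depp1, and Nnat at least 1.98-fold.

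**Figure D1:**
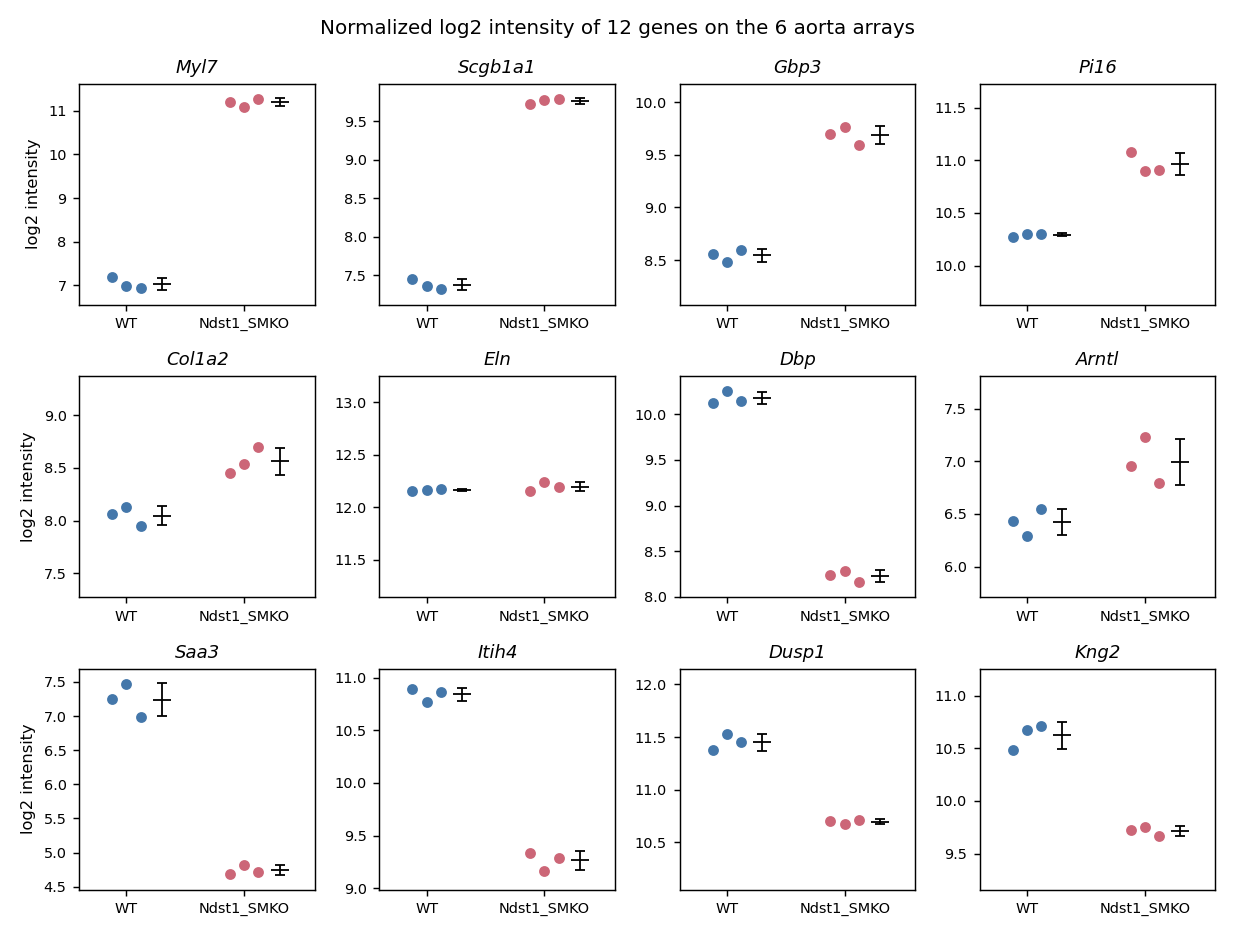
Normalized log2 intensity (vertical axis, a different range in each panel) of 12 genes on the 3 WT and 3 mutant (Ndst1_SMKO) arrays. Each point is 1 array, and the bar beside it is the mean with the standard deviation. Myl7 and Scgb1a1 lay far higher on all 3 mutant arrays, Dbp, Saa3 and Itih4 far lower, and the brightest Eln probe overlapped between genotypes.

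Of 17954 probes, 1336 passed the threshold, 776 higher and 560 lower in the mutant, and 507 of them differed by at least 1.5-fold. Counted by gene, 741 of 10076 passed, 465 higher and 276 lower, of which 72 rose and 15 fell at least 2-fold. Without the genes of the cell type lists 688 remained, 420 higher and 268 lower. Only 53 called genes were in those lists, so the count could not fall far. Muscle genes outside the lists, among them Cox6a2, Mybphl, Ttn and Mb, were still counted, so the 688 are not free of other tissues. The 3 values of each genotype did not overlap for 34.1% of the genes, where chance gives 10% if the arrays are independent samples. Repeat measurements of the same RNA within a genotype could exceed 10% without an effect of the genotype, so this share cannot show such an effect. Among the genes past the threshold, 300 had several detected probes. Of these, all probes passed in the same direction for 63, and for 1 gene a probe passed in the opposite direction. The share of higher calls depended on the scaling: 58.1% of the called probes were higher with quantile normalization, 80.7% with median scaling and 88.9% without normalization between arrays, where the median of all probes stood 0.13 higher in the mutant. Leaving out WT replicate 1, 2 or 3 left 538, 525 or 557 called probes, and leaving out mutant replicate 1, 2 or 3 left 440, 387 or 360.

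No heparan sulfate enzyme tested here passed the threshold, although that depended on the processing for some. None of the 23 detected genes of heparan sulfate chain synthesis and modification passed over all probes or adjusted over the list alone, and the list did not rank apart (median 0.04, camera adjusted p = 0.450). Ndst2, the paralog detected here, differed by 0.03 ± 0.11, and the probes of Ndst3 and Ndst4 were not detected on enough arrays to be tested. Hs3st1, a sulfotransferase acting later in the pathway, stood at 0.43 ± 0.10 (adjusted p = 0.0557) and passed under 8 of 18 alternatives (adjusted p = 0.00411 to 0.138). Extl2 (0.24 ± 0.07) passed under 6 and Sulf1 (0.26 ± 0.09) under 4. Hpse, which cleaves the chain, stood at -0.54 ± 0.16 (adjusted p = 0.0940). Of 11 genes of chondroitin and dermatan sulfate synthesis none passed either (adjusted p = 0.705). The core proteins that carry heparan sulfate ranked higher as a list (14 genes, median 0.25, adjusted p = 0.00896, but adjusted p = 0.102 with an estimated correlation and 0.0508 with median scaling, over alternatives 8.02e-05 to 0.102). Of these, 2 rose both over all probes and adjusted over the list alone: the cell surface glypican Gpc3 (0.76 ± 0.08, adjusted p = 0.00395) and Nrp1, a coreceptor for semaphorins and VEGF (0.34 ± 0.07, adjusted p = 0.0397), of which 1 of the 3 probes stood at 0.18. In the same arrays, adventitial fibroblast and endothelial markers ranked higher too (medians 0.36 and 0.21).

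Some elastic fibre and collagen genes rose. Of 17 detected elastic fibre and microfibril genes 6 rose over all probes and 7 adjusted over the list alone (median 0.16, camera adjusted p = 0.000995, adjusted p = 0.0824 with an estimated correlation). They were the fibre-associated Fbln1 (0.49 ± 0.07, adjusted p = 0.0126) and Fbln2, the microfibril proteins Mfap2 (0.47 ± 0.08), Mfap4 and Mfap5 (0.36 ± 0.07), and Emilin2. Eln, which encodes elastin itself and was singled out after its values were seen, had a brighter probe at 0.03 ± 0.07 (adjusted p = 0.80) and a second probe that passed at 0.65. Among 19 collagens 3 rose over all probes, Col1a2 (0.52 ± 0.09, adjusted p = 0.0259), Col6a1 (0.37 ± 0.08) and Col14a1 (its other probe at 0.08), and 7 adjusted over the list alone. The collagen list ranked higher (median 0.26, adjusted p = 0.000102, adjusted p = 0.0791 with an estimated correlation). In the same arrays, 11 of 17 adventitial fibroblast markers rose (median 0.36, adjusted p = 2.31e-08, adjusted p = 0.0509 with an estimated correlation), among them Pi16 (0.67 ± 0.08) and Pdgfra (0.41 ± 0.07), with 13 adjusted over the list alone. The lists overlap: 6 of the 17 fibroblast markers are in another list, among them Fbln1, Mfap5 and Col14a1, which count on both sides. Fbln2 and Mfap4 lay outside the naming rule and were chosen after their values were seen. Of the other called genes of these lists named here, Pi16 passed under every alternative, and the rest lost the threshold under several of 18. Fbln1 lost it under 3, Mfap2 and Emilin2 under 6, Pdgfra under 7, Col1a2 under 8, Mfap5 under 9, and Col6a1 and Col14a1 under 10. Pdgfra, Col1a2, Mfap5, Col6a1 and Col14a1 lost it whichever single array was left out.

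None of the other matrix lists passed. Of 21 matrix proteases and inhibitors 3 rose and 3 fell (5 and 3 adjusted over the list alone, adjusted p = 0.360). Mmp2, a gelatinase, was higher (0.51 ± 0.08), while the inhibitor Timp1 (-0.69 ± 0.09, adjusted p = 0.00752) and Mmp3, a stromelysin (-0.49 ± 0.09), were lower. Of 10 small leucine-rich and large chondroitin sulfate proteoglycans, Lum and Dcn rose and Cspg4, a marker of mural cells, fell (5 and 2 adjusted over the list alone, adjusted p = 0.203), and another probe of Dcn stood at -0.12. Pcolce2 rose among 15 genes of collagen maturation and crosslinking (2 adjusted over the list alone, adjusted p = 0.159). Mgp, an inhibitor of calcification, rose among 12 genes of the modulatory and repair matrix (2 adjusted over the list alone, adjusted p = 0.0671). Mgp (0.49 ± 0.07) and the chondrogenic factor Sox9 (0.52 ± 0.10) were the 2 that rose of 6 osteochondrogenic genes (3 adjusted over the list alone, adjusted p = 0.20).

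The contractile apparatus of smooth muscle did not move as a group (25 genes, median 0.04, adjusted p = 0.503). Cald1 rose with its brightest probe (0.75 ± 0.12, adjusted p = 0.0170), the only called one of 5 (lowest 0.13), and Lmod1 fell (-0.31 ± 0.07, adjusted p = 0.0472), both also adjusted over the list alone and both losing the threshold under some alternatives. Singled out after their values were seen, Myh11 stood at 0.04 ± 0.07 and the brightest probe of Acta2 at 0.02 ± 0.07, with its 5 probes spread from -0.63 to 0.35 and 1 of them past the threshold, higher. Of 31 receptors, channels and signalling genes of vascular tone 5 rose, 8 adjusted over the list alone (median 0.23, adjusted p = 0.000453, adjusted p = 0.0791 with an estimated correlation). The most changed were Pln, at least 4.06-fold higher, Atp2a2 (1.52 ± 0.08) and Ryr2 (1.31 ± 0.09), which handle calcium in heart muscle too and moved together with the cardiac markers. Another of the 3 probes of Atp2a2 stood at -0.17. Rgs4, a brake on G protein signalling, also rose (0.57 ± 0.10). Without Pln, Atp2a2 and Ryr2 the other 28 genes ranked higher with 2 past the threshold (median 0.15, adjusted p = 0.0203, adjusted p = 0.107 with an estimated correlation). Over the alternatives run for this list the adjusted p ranged from 1.24e-05 to 0.0791.

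Of the growth factor lists, that of TGF-beta and BMP signalling ranked higher. Adventitial fibroblast and endothelial markers ranked higher in the same arrays (medians 0.36 and 0.21, camera adjusted p = 0.0509 and 0.0824 with an estimated correlation). Of 31 genes of TGF-beta and BMP signalling 5 rose, the same number adjusted over the list alone (median 0.10, adjusted p = 0.0206, adjusted p = 0.206 with an estimated correlation 0.174 with the mean of a gene's probes and 0.0633 without WT replicate 2, over alternatives 0.00717 to 0.206). Fst, an activin antagonist (0.88 ± 0.08, adjusted p = 0.00192), the activin subunit Inhba (0.63 ± 0.12) and Ccn2, a TGF-beta target (0.37 ± 0.07), were among them. Of 29 growth factors that bind heparan sulfate and their receptors 3 rose, also adjusted over the list alone: the lymphatic growth factor Vegfc (0.91 ± 0.09, adjusted p = 0.00277), Igfbp5 (0.61 ± 0.08) and Pdgfra (list adjusted p = 0.227). Among 10 feedback targets of receptor tyrosine kinases Ccnd1 rose and Ier3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.455). Among 23 Wnt and hedgehog genes Dkk3 and Sfrp1 rose and Axin2, a target of Wnt signalling, fell by 0.51 (5 and 1 adjusted over the list alone, adjusted p = 0.203). Of 28 integrin and focal adhesion genes Fn1 alone rose (its other probe at 0.22 and not past the threshold), and none adjusted over the list alone (adjusted p = 0.532). Of 14 proliferation genes Mcm4 alone rose, 1 adjusted over the list alone (adjusted p = 0.705).

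Energy metabolism genes ranked slightly lower, in arrays in which brown and white adipocyte markers ranked lower too (medians -0.20 and -0.09, adjusted p = 0.0791 and 0.107 with an estimated correlation). The 33 genes of oxidative phosphorylation had a median of -0.07 (adjusted p = 0.0203, adjusted p = 0.102 with an estimated correlation), with Atp5k the single call (-0.37 ± 0.08, adjusted p = 0.0388, its other probe at -0.04) and none adjusted over the list alone. The list lost its call without WT replicate 1 (0.0523) or mutant replicate 1 (0.0547, over alternatives 9.41e-11 to 0.102). The 15 glycolysis genes had a median of -0.19 (adjusted p = 0.0323, adjusted p = 0.131 with an estimated correlation), where Pgam1 fell (-0.36 ± 0.08) and the muscle enolase Eno3 rose (1.70 ± 0.10), with 6 lower and 1 higher adjusted over the list alone. Its call was lost without WT replicate 1 (0.0823), mutant replicate 2 (0.0572) or mutant replicate 3 (0.0683, over alternatives 0.000301 to 0.131). Of 19 genes of sterol and fatty acid synthesis 3 rose, Msmo1 (0.45 ± 0.08), Sqle (0.45 ± 0.08) and Cyp51, all enzymes of the cholesterol pathway. Adjusted over the list alone 5 rose, and the list did not pass (adjusted p = 0.0753).

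Interferon response genes ranked higher, in arrays in which B cell, T cell and plasma cell markers ranked higher too (median 0.21, adjusted p = 0.0897 with an estimated correlation). Of 20 detected, 10 were higher over all probes and 11 adjusted over the list alone (median 0.51, adjusted p = 6.56e-07, adjusted p = 0.0509 with an estimated correlation). The guanylate binding proteins Gbp3 (1.14 ± 0.08, adjusted p = 0.000528) and Gbp2 (0.98 ± 0.08, its other probe at 0.60 and not past the threshold) and the chemokine Cxcl9 (1.14 ± 0.09) rose, while the immunoproteasome subunit Psmb8 rose by 0.50 ± 0.08 with its brighter probe and stood at -0.01 with the other. Inflammatory cytokines, chemokines and adhesion genes split, with 2 of 16 higher, among them Ccl5 (0.78 ± 0.12), and 3 lower, Saa3, Lcn2 and Ccl8 (-0.93 ± 0.10), against 5 and 3 adjusted over the list alone. The median of that list was 0.26, its mean -0.09 and its adjusted p = 0.482.

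**Figure D2:**
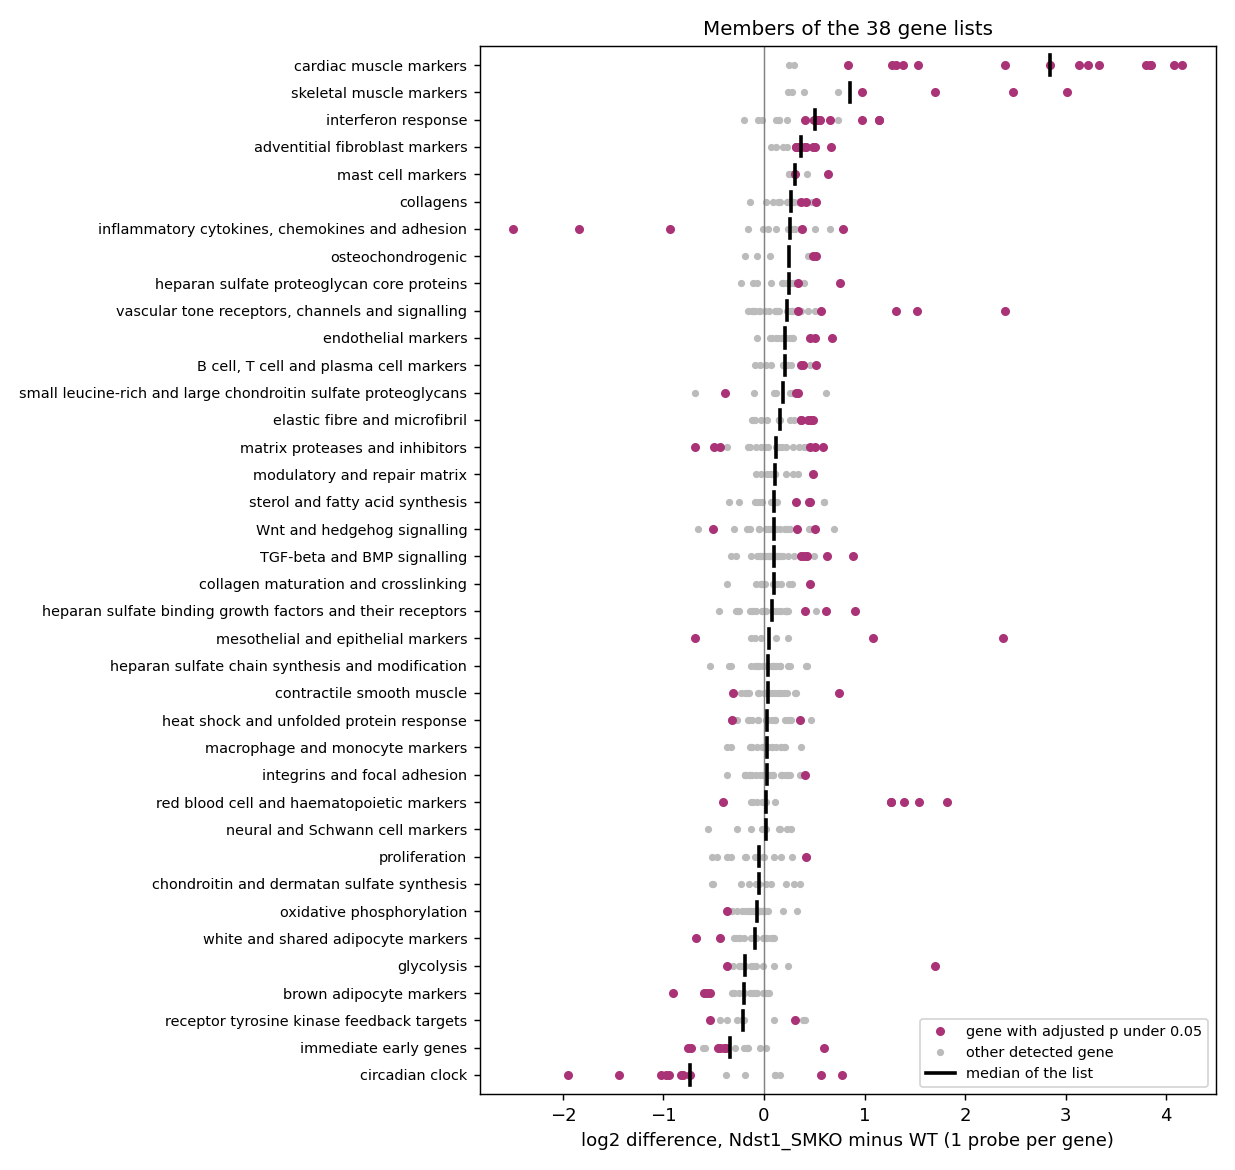
Log2 difference (mutant minus WT, horizontal axis) of every detected gene in the 38 lists, 1 probe per gene. Each row is a list, purple points passed the adjusted p threshold of 0.05, and black bars are list medians, from -0.73 for the circadian clock to 2.85 for cardiac muscle markers.

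Clock and immediate early transcripts differed between the genotypes. Of 15 circadian clock genes 8 fell and 2 rose, the same numbers adjusted over the list alone (median -0.73, adjusted p = 0.000115, adjusted p = 0.102 with an estimated correlation). The falls included Dbp, Nr1d1, Nr1d2 (-1.02 ± 0.09) and Per3 (at least 1.66-fold lower), and the rises were Npas2 (0.77 ± 0.16) and Arntl (0.57 ± 0.13), which peak at the opposite time of day and were chosen after their values were seen. Of 16 immediate early genes 6 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.34, adjusted p = 8.31e-05, adjusted p = 0.0791 with an estimated correlation). Dusp1 (-0.75 ± 0.08, adjusted p = 0.00280), Jun (-0.72 ± 0.10) and Egr3 (-0.44 ± 0.07) fell, and Klf6 rose (0.59 ± 0.08), although its other probe stood at -0.03. Heat shock and unfolded protein response genes did not move as a list (20 genes, adjusted p = 0.745, 2 higher and 1 lower adjusted over the list alone).

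Markers of other tissues also differed. Of 17 detected cardiac muscle markers 15 rose, 16 adjusted over the list alone (median 2.85, adjusted p = 1.17e-26, adjusted p = 0.0108 with an estimated correlation), and 15 of the 17 were detected on every WT array as well. Of 8 skeletal muscle markers 4 rose, 5 adjusted over the list alone (adjusted p = 2.62e-06, adjusted p = 0.0897 with an estimated correlation): Ckm (at least 4.15-fold higher), Pgam2 (3.01 ± 0.19), Eno3 and Tcap, all of which heart muscle also makes. Scgb1a1, a secretory protein of the airway lining, was 5.21-fold higher (2.38 ± 0.07, adjusted p = 1.09e-05) and Wfdc2 rose. Cyp2f2, another airway gene, fell by 0.68, and the 8 mesothelial and epithelial markers did not rank apart (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.276). Of 13 red blood cell and haematopoietic markers the neutrophil genes S100a8 (1.40 ± 0.08), S100a9 (1.26 ± 0.09), Camp (at least 2.70-fold), Ngp (at least 1.97-fold) rose, as did Ltf, and Slc4a1 fell (the last 2 chosen after their values were seen), with the same numbers adjusted over the list alone (adjusted p = 0.0189, adjusted p = 0.108 with an estimated correlation). That list lost its call under 7 alternatives, among them leaving out mutant replicate 1 (0.244), 2 (0.142) or 3 (0.375), with adjusted p between 8.02e-05 and 0.427 over the alternatives. The globins Hbb-bt (0.02 ± 0.07) and Hbb-bs (0.00 ± 0.07) were among the brightest probes in both genotypes and stood below WT past the threshold only in the authors' processed values (-0.17 each). Of 18 macrophage and monocyte markers and 9 neural and Schwann cell markers none passed with its brightest probe, nor adjusted over the list alone (adjusted p = 0.745 and 0.841), although 2 of the 3 probes of Lyz1 did (up to 0.59, against 0.08 for the brightest). The neural list had a median of 0.02 and a mean of -0.02.

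Endothelial markers ranked higher in the mutant (17 genes, 3 rose, 5 adjusted over the list alone, median 0.21, adjusted p = 9.10e-05, adjusted p = 0.0824 with an estimated correlation), with the tight junction protein Cldn5 at 0.51 ± 0.07 and Ptprb at 0.68 ± 0.12. Ptprb lost the threshold under 7 alternatives. The 3 brightest endothelial genes did not pass: Egfl7 (0.08 ± 0.07), Esam (0.21 ± 0.07) and Flt1 (0.12 ± 0.08). B cell, T cell and plasma cell markers also ranked higher (14 genes, 3 rose, 5 adjusted over the list alone, median 0.21, adjusted p = 0.00410, adjusted p = 0.0897 with an estimated correlation). The 3 were Cd52 (0.52 ± 0.07), H2-Ab1 (0.37 ± 0.07) and Coro1a (0.38 ± 0.09), while the T cell gene Cd8b1 passed under no alternative (-0.05 to 0.13). Mast cell markers ranked higher too (7 genes, 2 rose, 6 adjusted over the list alone, median 0.31, adjusted p = 0.000967, adjusted p = 0.0897 with an estimated correlation), where 1 of the 2 Kit probes rose (0.63 ± 0.08). Fat markers ranked lower. Of 18 brown adipocyte markers 4 fell, 5 adjusted over the list alone (median -0.20, adjusted p = 0.000170, adjusted p = 0.0791 with an estimated correlation): the kininogens Kng2 (-0.91 ± 0.09) and Kng1 (-0.60 ± 0.08), the kinase Pdk4 (-0.57 ± 0.08) and Cpn2. Of 18 white and shared adipocyte markers Pck1 and Aqp7 fell, 4 adjusted over the list alone (median -0.09, adjusted p = 0.0189, adjusted p = 0.107 with an estimated correlation). None of the 4 brightest fat genes passed: Cox8b (-0.09 ± 0.07), Cidea (0.02 ± 0.08), Cox7a1 (-0.07 ± 0.08) and Ucp1 (-0.25 ± 0.08), the last chosen after its values were seen. In the authors' processed values Cox8b (-0.25), Cidea (-0.21) and Cox7a1 (-0.30) were called lower. Only the cardiac list passed with an estimated correlation among the 19 lists that passed camera with the preset one (13 higher, 6 lower), while fry called 28 of the 38. The lost calls need not mean correlated genes. The estimate lay below the preset 0.01 for some of these lists, such as interferon response (-0.017) and collagens (-0.014). It lay above 0.01 for others, such as the clock (0.088) and skeletal muscle markers (0.215). Of 109 genes that the rule named and that passed, 51 passed under every alternative and 58 lost the threshold under at least 1. Of 44 such genes with several detected probes, 29 had a probe that did not pass.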

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

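Of the alternatives, all but the counts and lists without cell type, handling and heart calcium genes were chosen before the data were examined. No gene called by both the main setting and an alternative changed direction, and the count of called genes without the cell type and handling lists was 669. The number of called probes (1336), the number among them with a fold of at least 1.5 (507) and the number of called genes (741) moved by over 1.5 times as follows. Without background correction they were 3048, 128 and 1835, with normexp and an offset of 50 they were 2365, 200 and 1371, without normalization between arrays 2711, 871 and 1626, and with the authors' processed values 3493, 127 and 2116. Called probes and genes were 722 and 402 without a filter on dim probes, which tests more probes, 2017 and 1159 with a detection p under 0.01 on all 6 arrays, and 3086 and 1872 with trend and robust settings, and an unmoderated test gave 827 probes, 288 of them at 1.5-fold. Apart from the filters, the cause was not tested. Higher calls made up 50.5% of called probes without background correction, 41.5% in the authors' processed values, 49.8% with a detection p under 0.01 on all 6 arrays and 50.5% with trend and robust settings, against 58.1%. With 1 array left out, which leaves 2 samples in a genotype, called probes ranged from 360 to 557 (538, 525 and 557 without WT replicate 1, 2 and 3, and 440, 387 and 360 without mutant replicate 1, 2 and 3), probes at 1.5-fold from 305 to 412, called genes from 201 to 312.

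With the replicate number as a replicate block, 364 probes and 218 genes passed. Deviations of same-numbered samples from their genotype means correlated at -0.015, 0.011 and 0.020, which shows no pairing. A pairing is not excluded, since even 2 probes of the same gene hardly shared such deviations (mean correlation 0.0254). Array weights and the mean of a gene's probes kept all counts within 1.5 times; the latter gives no count of probes. Of the 19 lists, 1 passed with an estimated correlation. Leaving the genes of the cell type lists out of the other lists changed no call but removed at most 2 genes from any. Fry called the inflammatory list (median 0.26) in the lower direction (adjusted p = 0.00436; range over alternatives 0.00436 to 0.861), and the authors' processed values turned Cidea (-0.21), Hbb-bt (-0.17) and Hbb-bs (-0.17). The targeted gene gave no values under any setting, and the chip block was not run. Probes near the background limit what can be seen: their fold changes shrink with the offset. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. Only 1, the real one, gave 1336 probes (highest other 0), 741 genes (highest other 0), 507 probes at 1.5-fold (highest other 0) or 19 lists (highest other 4).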

Other observations

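The tests on heart muscle, brown fat, the added lists and genes outside the naming rule were chosen after results were seen, and the test on the clock after the falls of the Dbp, Nr1d1 and Per arm but before the values of the opposite arm. A list of acute phase genes, put together after 5 of its genes had been seen among the largest falls and so not independent of them, ranked lower in the mutant aortas (21 detected genes, 9 lower and 1 higher past the threshold, median -0.33, camera adjusted p = 8.68e-07, adjusted p = 0.00572 with an estimated correlation). Without those 5 the other 16 had a median of -0.20 (4 lower and 1 higher past the threshold, adjusted p = 0.0272, adjusted p = 0.0770 with an estimated correlation). Besides the 5 it included haptoglobin (Hp, -0.97 ± 0.09) and the orosomucoids Orm1 (-0.49 ± 0.08) and Orm2 (-0.62 ± 0.10). Brown and white adipocyte markers ranked lower in the same arrays (medians -0.20 and -0.09). Of the 21 genes 6 lay above 0, and Hamp, which also responds in the acute phase and was not put in the list, rose by 3.22. Hamp was among the largest rises, most of them genes of striated muscle, so its rise need not belong to this response. Of the 6 above 0, the fibrinogen chain Fgg, detected on no WT array, was at least 1.15-fold higher, and for the chain Fga, also detected on no WT array, 1 of 2 probes passed in that direction but not the brighter one (adjusted p = 0.0744).

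Single genes outside the lists also stood out. Cish, an inhibitor of cytokine signalling through STAT5, was 6.93-fold higher (2.79 ± 0.08, adjusted p = 6.35e-06). Mup3, a major urinary protein (1.93 ± 0.07, adjusted p = 2.43e-05), rose too. Igtp (1.53 ± 0.09) and Irgm2 (1.17 ± 0.08), GTPases induced by interferon gamma, rose with Gbp2, Gbp3 and Cxcl9.

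Heart muscle transcripts were higher in the mutant arrays, and normalization between arrays is argued against, since Myl7 stood at 4.29 without it. Skeletal muscle was not excluded: 3 fast skeletal genes had a median of 0.28, none past the threshold, but lay near the detection limit, each missed on at least 1 WT array. Their means in the mutant were low too (Acta1 5.40, Mylpf 5.29, Casq1 5.43), against 11.19 for Myl7. These 3, of 12 genes listed, thus gave no sign of abundant fast skeletal muscle, but how their probes respond to such tissue was not tested. Heart muscle tissue in the mutant samples and a change of cell state with the genotype cannot be told apart, since the 88.2% of detected cardiac markers that were higher restates the pattern, with the abundant Actc1 and Myl4 at mean log2 values of 11.55 and 12.53 in the mutant against 7.71 and 9.20 in WT; 15 of the 17 markers were detected on all WT arrays too, and 2 are in another list. The 5 detected atrial genes, listed after the data had been seen, had a median of 3.81. Of these, Myl7, Sln, Mybphl and Myl4 were already among the largest rises, so the median restates them, and Nppa stood at 2.85. The ventricular genes Myl2 and Myl3 stood at 0.30 and 0.83, Myl3 past the threshold (limma adjusted p = 0.0159). Any such muscle may be of atrial type, which was not tested on independent genes. The raised markers deviated by -0.02 to 0.01 on average between the 3 mutant arrays.

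Clock transcripts were shifted between genotypes. A smaller share of brown fat is not excluded as a part of the shift. Its markers had a median of -0.20, where the 8 detected genes of the Dbp, Nr1d1 and Per arm had a median of -0.96 (-0.89 with Per3 at its bound). The 18 detected brown fat markers did not move together, however, so their median cannot measure that share. Of these, 4 fell past the threshold, among them Kng2 (-0.91), and 3 stood above 0. Collection at another time of day may account for the shift, since the opposite arm (Arntl, Npas2 and Clock) had a median of 0.57 while the other arm fell. No label gives a time of day, and an effect of the genotype on the clock stays open, as untested.

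The 3 arrays of a genotype lay close together, with correlations of 0.991 to 0.993 within and 0.982 to 0.984 between genotypes. Separate mice that differ in clock, immediate early, blood, lymphocyte and fat transcripts are argued against: those 93 genes had 0.928 times the within-genotype standard deviation of genes matched on mean value (random sets 0.879 to 1.14). In 884 genes with 2 bright probes, the deviations of both probes within a genotype correlated at 0.0254 on average (1000 random re-pairings -0.06 to 0.05), although their differences between genotypes correlated at 0.810 across genes, which are not independent replicates. Both are consistent with repeat measurements of the same RNA, or of the same pool, which was not tested apart. If that holds, the p-values above compare 1 RNA of each genotype and cannot speak for mice.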
